A study of Mus musculus with 7 samples.

How the data were processed

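Total RNA from flash-frozen mouse hearts was extracted with Trizol, its quality was assessed on an Agilent Bioanalyzer, and it was converted to biotin-labelled cRNA with the Affymetrix one-cycle 3' kit, per the labels' protocols. The deposited values are log2 signals per probe set, a unit read from the values, which lie between 3.20 and 14.28 on every array; per the submitters' processing notes the Affymetrix software GCOS was used, with no version or role stated. The method of summarization, the scaling or normalization between arrays and any filter are not given in the sources used here. Array medians lay within the 0.15 log2 limit that had been set for using the values as deposited, so the comparison rests on the deposited log2 values with no further scaling. Scanner files were not used here.

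Genes were named through the platform's probe annotation, with symbols checked by Entrez number against RefSeq genes of GRCm38.p6. Of 22626 probe sets 20380 had 1 gene symbol, 691 several and 1555 none; Entrez numbers of 20351 were found and 0 symbols needed an update. Probe sets with several symbols or none were tested but never named. Probe sets whose mean over the 7 arrays was at or above the 40th percentile (log2 5.74) were kept, which left 13576. A gene was represented by the kept probe set with the highest mean over the 7 arrays among those with exactly 1 symbol, giving 8404 genes.

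KLF15-null (n = 3) and WT (n = 4) arrays were compared with limma 3.58.1 in R 4.3.3, by a linear model with no covariate and empirical Bayes moderation with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all kept probe sets and a threshold of 0.05. Every adjusted p given for a gene comes from this limma model. For Klf15 an exact permutation test over the 35 splits of the 7 arrays was run as well. There were 44 gene lists, of pathways, stress responses and cell types, and the 40 with at least 5 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, adjusted over the 40 lists. With a correlation estimated from the data no list passed, the lowest adjusted p being 0.853. In 4 lists too few genes were measured for a test: of proliferation genes 1 of 4 was called (Mcm6 at 0.30), of lung epithelium markers 1 of 4 (Scgb3a1 at 1.05), of mesothelium markers 1 of 2 (Aldh1a2 at 1.92) and of thymus markers 1 of 3 (Rag2 at -0.50). Members past the threshold are counted among all kept probe sets and, separately, adjusted over the list alone.

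The lists, the tests, the filter and the rule for named genes were fixed before the data were examined. The rule took Klf15, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with all 3 KLF15-null values on one side of all 4 WT values and the higher group mean at or above the median of all probe sets (2105 genes higher and 1456 lower were eligible), the gene with the smallest p in each direction, and up to 4 members per list by smallest p. Genes without a name beyond a clone or model number were counted and not named. Where a gene outside the rule is named, the text says that it was chosen after its values were seen, or it serves as a sex-linked or probe set example. Krüppel-like factor family members, Y-linked genes and Xist were taken from the same annotation.

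The procedure was tested on simulated data for the KLF15-null against WT comparison, with 13576 probe sets and 200 of them changed. It recovered 48% of changes of 0.5 on the log2 scale, 98% of those of 1, and 100% of those of 2 and of 3, and 7 unchanged probe sets were called, 3.89% of all calls. A list shifted by -0.6 was called and 0 other lists were. The real comparison called 6872 probe sets, far more than the 200 changed in the simulation. With few changes the adjustment asks for a smaller unadjusted p, so the shares recovered do not carry over to the real comparison. The simulated probe sets varied independently, while members of a real list are correlated (estimated at 0.56 for the branched-chain list). The simulation therefore cannot show how often a list is called falsely in these data. Whether replicate numbers pair the samples was checked by correlating the deviations from the group means of arrays with the same number, which gave -0.11, 0.00 and 0.19, so the numbers were not taken as pairs.

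Alternatives were no filter, a filter at the 60th percentile, quantile, cyclic loess and median scaling, no intensity trend, array weights, gene-specific probe sets preferred, a threshold of 0.1, a replicate block, each array left out, an estimated correlation and limma's fry. Chosen after seeing the data were the mean of a gene's probe sets, leaving out genes with opposite probe sets, a 2-fold limit, leaving out _x_at probe sets, the probe set brightest in WT for each gene, and an exact permutation of list means. The planned offsets before taking logs did not apply, since the table is already on the log2 scale. A planned RNA quality measure from 3' and 5' control probe sets was not analysed here because those probe sets are not in the table used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.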

Results

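RNA of whole hearts was measured on 7 Affymetrix 3' expression arrays, 4 from wild-type mice (WT) and 3 from mice without a functional gene for Krüppel-like factor 15 (KLF15-null), a zinc-finger transcription factor of heart, skeletal muscle and liver. All mice were labelled as male, 3 to 4 months old and fasted for 18 h before the heart was taken. The table held 22626 probe sets per array, with array medians between 6.22 and 6.33 on the log2 scale. The 98th percentile lay between 11.43 and 11.74 on the WT arrays and between 11.86 and 12.02 on the KLF15-null arrays. The brightest 10% of the probe sets had a median difference of 0.30 (KLF15-null minus WT, as for all differences given here). Pearson's r over all probe sets was 0.995 to 0.997 between WT arrays, 0.986 to 0.993 between KLF15-null arrays and 0.942 to 0.964 between the genotypes. Xist, the RNA that silences the inactive X chromosome of female cells, lay at the 91.4th percentile on the 7-array mean (log2 9.54) on its brightest probe set, and at the 86.8th and the 33.6th on its other 2, the last one below the filter level used here. The 9 gene-specific probe sets of Y-linked genes, Eif2s3y, Kdm5d, Uty and Usp9y among them, all lay at or below the 28.6th percentile on the 7-array mean, and a cross-hybridizing _x_at probe set of Sry lay at the 53.0th.

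The comparison asked which cardiac genes differ between KLF15-null and WT mice after an 18 h fast. All 7 arrays came from fasted mice, so whether a difference depends on the fast was not tested. Of all 8404 genes tested 2301 were higher and 1643 lower, and counts of list members are to be read against these shares. In KLF15-null hearts 16 of 22 genes of branched-chain amino acid breakdown were lower and 1 higher, Bckdhb and Dbt of the branched-chain ketoacid dehydrogenase having the smallest p of the list. Of 16 genes of other amino acid breakdown 8 were lower, Fah and Aldh4a1 among them, and 2 higher. Both lists passed camera with a preset correlation between genes. Neither did with an estimated one (adjusted p = 0.853 for each, 0.178 and 0.0365 unadjusted) or by an exact permutation (adjusted p = 0.0571 for each). There the number of splits is the limit: each had the smallest exact p that 35 splits allow, 0.0286, as did 20 of the 40 lists in all. The other amino acid list also missed camera's threshold under the stricter filter (adjusted p = 0.0515). Ppara and Ppargc1a, regulators of fatty acid oxidation and mitochondrial genes, fell by 2.13 and 1.80 on the log2 scale, although 2 dimmer probe sets of Ppargc1a differed by 0.04 and -0.18, not past the threshold. Hadha and Echs1 of β-oxidation also fell, in a list with 6 of 21 genes lower, 3 higher and 12 not past the threshold. Neither that list (adjusted p = 0.0991) nor that of the regulators (adjusted p = 0.164) passed camera in the main comparison. With limma's fry the regulator list passed (adjusted p = 0.0256) and the β-oxidation list did not (adjusted p = 0.113). Of 15 cytokine and acute-phase genes 13 were higher, with Ccl2 by 2.71 on the log2 scale. Socs3 rose 18.7-fold on a cross-hybridizing _x_at probe set and 3.05-fold on its gene-specific one. The cytokine and acute-phase list too passed camera with the preset correlation but not with an estimated one (adjusted p = 0.853, 0.0811 unadjusted). By exact permutation it had an adjusted p of 0.0571, under the same limit. Of the macrophage and monocyte markers 7 of 15 were higher and 2 lower, and of the neutrophil markers 3 of 7 were higher, with neither list past camera's threshold. The 3 higher neutrophil markers are also members of the cytokine and acute-phase list, so they add no separate evidence. Slc2a1, the basal glucose transporter, and Myh7, the β-myosin heavy chain, rose, and Slc2a4, the insulin-responsive glucose transporter, fell.

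Klf15 itself had a mean log2 signal of 8.87 ± 0.19 (SD, n = 4) in WT and 6.33 ± 0.17 (SD, n = 3) in KLF15-null hearts, a difference of -2.54 (SE 0.13, adjusted p = 1.26e-06). All 3 KLF15-null arrays lay below all 4 WT arrays, and the exact two-sided permutation p was 0.0286, the smallest that 35 splits of 7 arrays allow. Klf15 has a single probe set on the array. Since the deleted part of the gene is not given in the sources used here, this value may check the genotype labels or may check nothing. Of 13576 probe sets bright enough to be tested, 3637 were higher and 3235 lower in KLF15-null hearts. Counted as genes, 2301 were higher and 1643 lower of 8404, and 608 and 293 of these by at least 2-fold, a limit set after the counts were seen. Higher calls made up 52.9% of the called probe sets and 58.3% of the called genes, against 63.3% and 69.9% after each array was centred on its median, 49.0% and 53.3% after cyclic loess normalization and 48.6% and 55.5% without _x_at probe sets, so which direction held the majority of probe sets depended on the processing. The excess of higher genes also depended on the probe set that stands for a gene, ranked here on all 7 arrays, KLF15-null included. Higher calls made up 54.4% of called genes with the probe set brightest in WT. They made up 52.2% with gene-specific probe sets preferred and 51.5% with the mean of a gene's probe sets. Among probe sets, 1026 were higher and 911 lower by at least 2-fold. Complete separation of the 3 KLF15-null from the 4 WT values was found for 53.0% of the probe sets tested, where chance gives 5.71%.

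**Figure D1:**
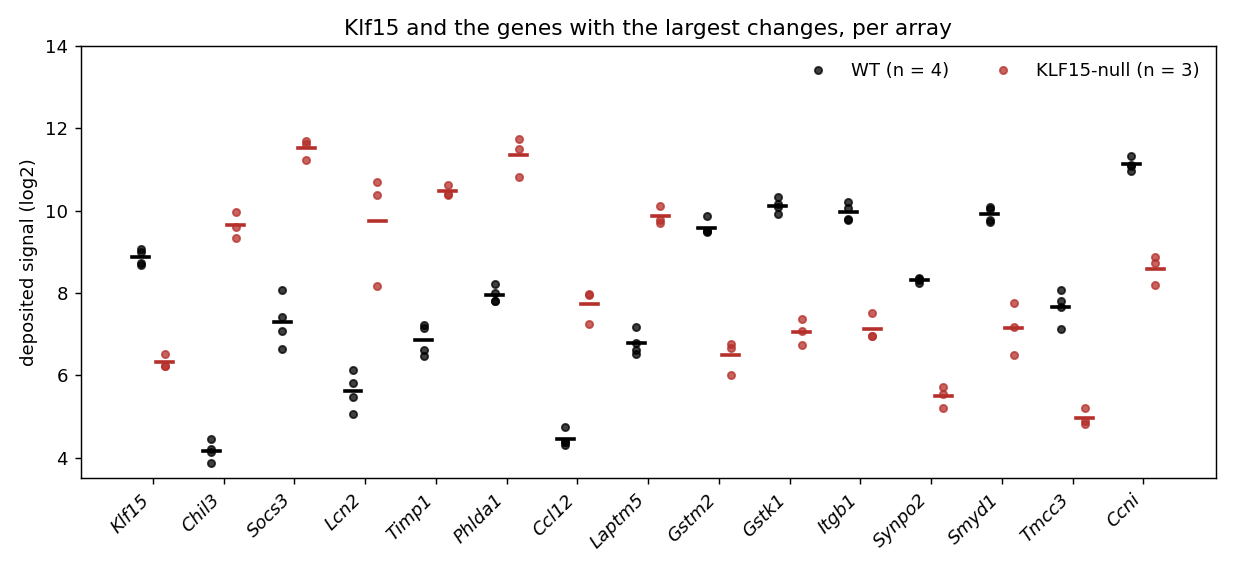
Log2 signal (y axis) of Klf15, of 7 of the genes with the largest rises and of 7 with the largest falls. Points are arrays and bars group means, for WT (black, n = 4) and KLF15-null (red, n = 3); for every gene shown the 3 KLF15-null values lie on one side of the 4 WT values, from 9.64 against 4.16 on average for Chil3 to 6.48 against 9.58 for Gstm2.

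The largest recorded difference among the rises was that of Chil3, which codes for a chitinase-like protein of alternatively activated macrophages, at 5.48 on the log2 scale (SE 0.17, adjusted p = 9.46e-08), also the smallest p of any rise among the probe sets that stand for genes. The table holds no detection calls, and the WT means of Chil3 (4.16), Ccl12 (4.45), Ch25h (4.80), Ms4a6d (5.13), Nfil3 (5.52), Lcn2 (5.62), Ccl7 (5.64) and Chga (5.68) lay below the filter level of 5.74. So did the KLF15-null means of Tmcc3 (4.97), Kcnip2 (5.12), Acot2 (5.15), Mccc2 (5.44), Synpo2 (5.50), Cacnb2 (5.51), Dusp18 (5.61), Apoa1 (5.64) and Apoa2 (5.68). For all of these the difference is a lower limit that background may set, and their order by size means little. Socs3, the feedback inhibitor of interleukin-6 family signalling, rose by 4.22 on the log2 scale, and Osmr, the oncostatin M receptor, by 3.08. Lcn2 (lipocalin 2, an acute-phase protein) rose by 4.13 with a wide spread among KLF15-null arrays (SD 1.38, n = 3). Timp1, a metalloproteinase inhibitor, rose by 3.60, the monocyte chemokine gene Ccl12 by 3.27, and the leukocyte genes Laptm5 and Ms4a6d by 3.08 and 3.02. Phlda1, Plscr1, Ch25h (cholesterol 25-hydroxylase) and the immediate early gene Egr1 rose by 3.39, 3.08, 3.03 and 2.98. The values given for Socs3 and Laptm5 came from cross-hybridizing _x_at probe sets. Other probe sets of Laptm5 differed by -0.14, not past the threshold, and 1.08. The gene-specific probe set of Socs3 rose by 1.61 (KLF15-null SD 1.06, n = 3) and a further _x_at one by 3.49.

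Among genes eligible for naming, each judged on its probe set brightest over the 7 arrays, the glutathione transferase genes Gstm2 and Gstk1 had the largest falls, at -3.10 and -3.06 (SE 0.18 and 0.16). Dimmer probe sets of other genes fell further or with a smaller p, such as one of Txnip at -4.52, named after its value was seen. Itgb1, the β1 integrin, fell by 2.83, with its other probe sets at -2.41 and -2.91. Synpo2, which codes for a Z-disc protein, fell by 2.82 and Smyd1, a muscle-specific methyltransferase needed for myofibril assembly, by 2.76. Fbln1, which codes for the matrix protein fibulin 1, fell by 2.47 and Pcmtd1, with the smallest p of any fall on that probe set (adjusted p = 4.45e-07), by 2.39. Tmcc3, Dusp18 and Get3 (an ATPase that targets tail-anchored proteins to the endoplasmic reticulum) fell by 2.70, 2.51 and 2.46. Ccni, the cyclin I gene, fell by 2.53 on its brightest probe set and by 1.86 on another, while yet another rose by 0.41.

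Branched-chain amino acid catabolism was the metabolic list with the smallest camera p at the preset correlation. With an estimated correlation the other amino acid list had the smaller unadjusted p (0.0365 against 0.178), as it had with fry (0.000181 against 0.00128). Of the 22 measured branched-chain genes 16 were lower, 1 higher and 5 not past the threshold, with the same 16 and 1 adjusted over the list alone. The median difference was -0.59, and 11 were lower after median centring and 19 after quantile or cyclic loess normalization. Bckdhb fell by 1.83 (SE 0.12), Dbt by 1.33, Pccb (propionyl-CoA carboxylase) by 1.29 and Mccc2 (methylcrotonyl-CoA carboxylase) by 1.03. All 4 had adjusted p at or below 3.99e-05. The exception, named after its value was seen, was Hibch at 0.32, and its second probe set differed by -0.04. Limma's camera test gave the list an adjusted p of 1.53e-05 with a preset correlation between genes, and adjusted p = 0.853 with an estimated correlation. Other amino acid catabolism had 8 genes lower, 2 higher and 6 not past the threshold of 16 (8 and 2 adjusted over the list alone). Its median was -0.41, and it had an adjusted p of 0.0139 with the preset and adjusted p = 0.853 with an estimated correlation. Fah of tyrosine breakdown fell by 1.67, Aldh4a1 of proline breakdown by 1.52 and Gcdh of lysine breakdown by 1.03, while Odc1, the rate-limiting enzyme of polyamine synthesis, rose by 1.28. The other amino acid list missed the threshold when probe sets under the 60th percentile were left out (adjusted p = 0.0515).

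**Figure D2:**
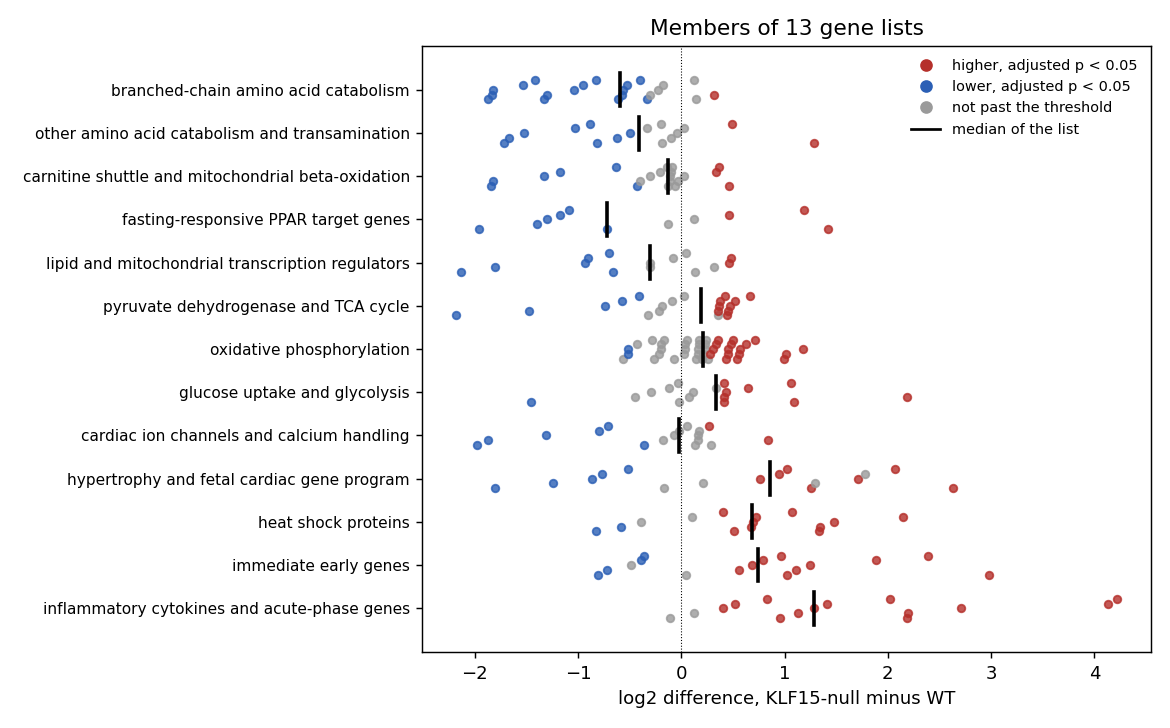
Log2 difference, KLF15-null minus WT (x axis), of each measured member of 13 gene lists, with a point per gene (red higher, blue lower, grey not past an adjusted p of 0.05) and a black line at the list's median. The medians run from -0.72 for fasting-responsive PPAR target genes and -0.59 for branched-chain amino acid catabolism to 1.28 for inflammatory and acute-phase genes; those of oxidative phosphorylation, glycolysis and the TCA cycle are positive here and negative after quantile or cyclic loess normalization.

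Genes of fatty acid handling moved both ways and no list of them passed camera's threshold in the main comparison, while 3 did after quantile and after cyclic loess normalization. On the deposited values limma's fry called the PPAR target list (adjusted p = 0.0126) and the regulator list (adjusted p = 0.0256) lower. In the carnitine shuttle and mitochondrial β-oxidation list 6 of 21 genes were lower, 3 higher and 12 not past the threshold (6 and 2 adjusted over the list alone; adjusted p = 0.0991). Hadha of the trifunctional protein fell by 1.84, Echs1 by 1.82, Crat (carnitine acetyltransferase) by 1.33 and Cpt1a, the liver-type carnitine palmitoyltransferase, by 1.17. A dimmer probe set of Cpt1a rose by 0.53. After quantile and after cyclic loess normalization the same list had 17 genes lower and none higher, and passed with adjusted p of 5.18e-07 and 1.30e-06. On the deposited scale it also passed without _x_at probe sets (7 lower, 2 higher, adjusted p = 0.0480), with a replicate block and without WT array 4. Among 11 measured fasting-responsive targets of the PPAR receptors 6 were lower, 3 higher and 2 not past the threshold, likewise over the list alone (adjusted p = 0.164, against 0.0329 after quantile and 0.0223 after cyclic loess normalization). Their median was -0.72, and -0.32 with the mean of a gene's probe sets (6 lower, 2 higher, adjusted p = 0.0875). The acyl-CoA thioesterases Acot1 and Acot2 fell by 1.96 and 1.40, and the lipid droplet protein gene Plin2 rose by 1.42. Of 14 lipid and mitochondrial regulators 6 were lower, 2 higher and 6 not past the threshold (7 and 3 over the list alone; adjusted p = 0.164). Rxrg stood at -0.70 and Ppargc1b at -0.91 beside Ppara and Ppargc1a. Fatty acid uptake and activation had 3 genes lower, 3 higher and 4 not past the threshold of 10, as over the list alone (adjusted p = 0.751). Slc27a1 fell by 1.75 and Cd36 by 0.74, and the acyl-CoA synthetase genes Acsl4 and Acsl5 rose by 1.75 and 1.02. Triglyceride storage and lipolysis had 2 of 15 genes lower, 1 higher and 12 not past the threshold, the same over the list alone (adjusted p = 0.421). After quantile normalization 7 were lower (adjusted p = 0.0536), after cyclic loess normalization 5 (adjusted p = 0.0819) and with the mean of a gene's probe sets 6 (adjusted p = 0.112). The hormone-sensitive lipase gene Lipe fell by 1.12 and Plin3 by 1.06. Peroxisomal oxidation had 2 of 8 lower, Pex11a at -0.59 and Crot at -0.47, with 6 not past the threshold and none called over the list alone (adjusted p = 0.402). Each of these 2 calls was lost when certain single arrays were left out, as given below. After quantile normalization 6 of the 8 were lower (adjusted p = 0.0329) and after cyclic loess normalization 5 (adjusted p = 0.0476). With the mean of a gene's probe sets the direction turned, with 2 higher, 2 lower and a median of 0.07 against -0.21 (adjusted p = 0.780).

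Glucose uptake and glycolysis had 8 of 17 genes higher, 1 lower and 8 not past the threshold, the same over the list alone (adjusted p = 0.389). On its brightest probe set Slc2a1 rose by 2.18, and another differed by 0.20, not past the threshold. Pfkp rose by 1.10 and Pgam1 by 1.06. Slc2a4 fell by 1.45, and by at least 3.85 on a second probe set, whose KLF15-null mean of 5.65 lay below the filter level. In the pyruvate dehydrogenase and TCA cycle list 9 of 20 genes were higher, 5 lower and 6 not past the threshold (10 and 5 over the list alone; adjusted p = 0.896). The list's median was 0.19 and its mean -0.09. Suclg2, the GTP-specific succinyl-CoA ligase subunit, fell by 2.18 and Idh3a of isocitrate dehydrogenase by 1.48, while Dlat and Sucla2 rose by 0.67 and 0.52. The 2 probe sets of Dlat that are brighter in WT differed by 0.06 and 0.02, not past the threshold. Oxidative phosphorylation had 17 of 43 genes higher, 2 lower and 24 not past the threshold, likewise over the list alone (adjusted p = 0.164). The complex I genes Ndufa2, Ndufa5, Ndufs7 and Ndufb3 rose by 1.18, 1.02, 0.99 and 0.63. The direction of all 3 lists depended on array scaling, and that of the TCA cycle list also on the choice of probe set. After cyclic loess normalization the medians were -0.02 for glycolysis, -0.23 for the TCA cycle (adjusted p = 0.0315) and -0.24 for oxidative phosphorylation (adjusted p = 0.00246). After quantile normalization they were -0.05, -0.20 (adjusted p = 0.0329) and -0.04. Oxidative phosphorylation had 5 genes higher and 23 lower after cyclic loess normalization, and 11 and 13 after quantile normalization. The TCA cycle list had 1 higher and 10 lower after each. Glycolysis had 4 higher and 6 lower after cyclic loess and 3 and 5 after quantile normalization. On the deposited scale the median of the TCA cycle list was -0.20 with gene-specific probe sets and -0.03 with the mean of a gene's probe sets, and with that mean oxidative phosphorylation was called higher (17 genes higher, 1 lower, adjusted p = 0.0286).

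Of 16 genes of cardiac hypertrophy and the fetal program 7 were higher, 5 lower and 4 not past the threshold, the same over the list alone (adjusted p = 0.620). Myh7 rose by 2.07 and Rcan1, a calcineurin target, by 2.63, though a second probe set of Rcan1 fell by 1.20. The cardiac transcription factor genes Gata4 and Gata6 fell by 1.81 and 1.24. Ion channels and calcium handling had 6 of 17 genes lower, 2 higher and 9 not past the threshold, as over the list alone (adjusted p = 0.309). After cyclic loess normalization 10 were lower (adjusted p = 0.0193), and with the mean of a gene's probe sets 8 (adjusted p = 0.0474). Kcnip2, the subunit of the transient outward potassium current and a known KLF15 target, fell by 1.97. The calcium channel subunit genes Cacnb2 and Cacna2d1 fell by 1.87 and 1.31, and the potassium channel gene Kcnj3 by 0.79. Extracellular matrix genes had 8 of 26 higher, 3 lower and 15 not past the threshold (7 and 3 over the list alone; adjusted p = 0.699). Timp1, Ccn2 (1.64) and Tgfb2 (0.98) were higher and Tgfb3 lower at -0.74. The list's median was -0.02 and its mean 0.27.

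Inflammatory cytokine and acute-phase genes were the only list called higher by camera in the main comparison. Of 15 measured genes 13 were higher, none lower and 2 not past the threshold, as over the list alone. The median was 1.28 (adjusted p = 6.25e-05 with the preset and adjusted p = 0.853 with an estimated correlation). Beside Socs3, the monocyte chemokine genes Ccl2 and Ccl7 rose by 2.71 and 2.19 and S100a8, a calprotectin subunit of neutrophils and monocytes, by 2.19. Immediate early genes had 10 of 16 higher, 4 lower and 2 not past the threshold (10 and 5 over the list alone; adjusted p = 0.313). Fos rose by 2.38, Atf3 by 1.89 and Myc by 0.97. Heat shock proteins had 10 of 14 higher, 2 lower and 2 not past the threshold, likewise over the list alone (adjusted p = 0.0772). The list was called higher without a filter, without _x_at probe sets (adjusted p = 0.0480) and without WT array 2 or 3, and was further from the threshold with the mean of a gene's probe sets (7 higher, 3 lower, adjusted p = 0.437). Hspa1b rose by 2.15, Hsph1 by 1.48, Hsp90aa1 by 1.33 and Hspa8 by 1.08. Another probe set of Hsph1 fell by at least 1.07, to a KLF15-null mean of 5.72 below the filter level, and one of Hsp90aa1 by 1.04. The unfolded protein and integrated stress list had 8 of 16 higher, 3 lower and 5 not past the threshold, as over the list alone (adjusted p = 0.309). Hspa5 rose by 1.19 and Ddit3 by 0.78, and Xbp1 and Hsp90b1 each had probe sets called both ways (Xbp1 1.19 and -1.75). Oxidative stress genes had 7 of 13 higher, 3 lower and 3 not past the threshold, as over the list alone (adjusted p = 0.435). The metallothionein genes Mt2 and Mt1 rose by 2.75 and 1.50 and Srxn1 by 1.01, and Gstm1 fell by 1.52. Interferon-stimulated genes had 6 of 15 higher, 1 lower and 8 not past the threshold, as over the list alone (adjusted p = 0.309). Ifit1 rose by 1.06 and Ifi27l2a by 0.94, and Irf9 fell by 0.47. The brightest probe set of Rsad2 rose by 0.70 and another fell by 1.07.

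Insulin and growth factor signalling had 8 of 17 genes lower, 3 higher and 6 not past the threshold, as over the list alone (adjusted p = 0.164). It passed after quantile (adjusted p = 0.0329) and cyclic loess normalization (adjusted p = 0.0402) and with the mean of a gene's probe sets (adjusted p = 0.0312). Pik3r1 and Tsc2 fell by 1.54 and 1.47 and the insulin-like growth factor receptor gene Igf1r by 0.79, and Eif4ebp1 rose from a mean log2 signal of 9.95 to 10.95. The probe set of Eif4ebp1 brightest in WT differed by 0.08, not past the threshold, and a dimmer one by 0.30. Atrophy and autophagy had 4 of 16 lower, 2 higher and 10 not past the threshold (3 and 2 over the list alone; adjusted p = 0.589). With gene-specific probe sets 7 were lower and none higher, with a median of -0.45 against -0.05 (adjusted p = 0.0903), and after quantile or cyclic loess normalization 7 were lower and 3 higher. The ubiquitin ligase gene Fbxo32 fell by 1.67, Sqstm1 by 1.18 and Ulk1 by 0.86, and Map1lc3b rose by 1.16. Other probe sets of Map1lc3b differed by 0.60 and by -0.57, the latter not past the threshold. Glucocorticoid receptor targets had 8 of 18 higher, 4 lower and 6 not past the threshold, as over the list alone (adjusted p = 0.435). The 4 with the smallest p were Mt2, Mt1, Cebpb (1.54) and Lcn2, and all but Cebpb also belong to the stress lists used here. Among clock genes 3 of 13 were higher, 3 lower and 7 not past the threshold, as over the list alone (adjusted p = 0.473). Nfil3 rose by 1.04 and Bhlhe40 by 0.84, and Per1 fell by 0.95 and Hlf by 0.74. Other Krüppel-like factors had 4 of 8 higher, 1 lower and 3 not past the threshold, as over the list alone (adjusted p = 0.676), against 1 higher and 2 lower with the mean of a gene's probe sets. On the probe sets brightest over the 7 arrays Klf7 rose by 1.20, Klf10 by 0.84 and Klf13 by 0.65, and Klf3 fell by 0.49. The probe set of Klf7 that is brightest in WT differed by 0.07, not past the threshold, and a dimmer one fell by 0.93.

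Markers of the cell types a heart sample can hold gave no list past camera's threshold on the deposited values; limma's fry called neutrophil (adjusted p = 0.0164) and white adipocyte markers (adjusted p = 0.0370). Macrophage and monocyte markers had 7 of 15 higher, 2 lower and 6 not past the threshold, as over the list alone (median 0.36, adjusted p = 0.309). Ptprc rose by 1.72, Cd14 by 1.64 and Lyve1 by 1.05, and C1qa fell by 1.24. The other lower marker, C1qb, had probe sets called both ways, its dimmer _x_at ones rising by 0.59 and 1.74. Of 7 neutrophil markers 3 were higher (S100a8, Lcn2 and S100a9, the last by 1.41) and 4 not past the threshold, as over the list alone. Their median was -0.02 and their mean 1.07 (adjusted p = 0.470). The 3 higher ones are also members of the inflammatory list, which bears on the fry call of the neutrophil list as well. Endothelial markers had 4 of 16 lower, 1 higher and 11 not past the threshold, as over the list alone (adjusted p = 0.459). Pecam1 fell by 2.24, Emcn by 1.44 and Tie1 by 0.77. Flt1 stood at 0.85 with another probe set called the other way. Fibroblast markers had 4 of 15 lower, 3 higher and 8 not past the threshold, as over the list alone (adjusted p = 0.389). Beside Fbln1, Lum fell by 1.38, Dcn by 1.25 and Ddr2 by 0.89. Smooth muscle and pericyte markers had 3 of 14 lower, 1 higher and 10 not past the threshold, as over the list alone (adjusted p = 0.459). Abcc9 fell by 1.53, Myh11 by 1.44 and Smtn by 0.87. Pdgfrb stood at 1.71 on its brightest probe set and at -0.43 on another. Cardiomyocyte markers had 3 of 18 higher, 2 lower and 13 not past the threshold (0 and 1 over the list alone; median 0.10, adjusted p = 0.809). Actn2 stood at -0.65, Ttn at -0.38, Ckmt2 at 0.36 and Csrp3 at 0.35. After cyclic loess normalization 15 of the 18 were lower, the median was -0.35 (adjusted p = 2.38e-05), and Ckmt2 and Csrp3 stood at -0.10 and -0.09. Atrial markers had 2 of 9 higher, 3 lower and 4 not past the threshold, as over the list alone (adjusted p = 0.751). Their median was 1.24, the value of an _x_at probe set of Clu, and 0.30 without such probe sets (1 higher, 3 lower); the test ran downward in both cases. Nppa rose by 1.71, Clu stood at 1.24 on that probe set and at 0.30, not past the threshold, on its only one of another class, and Nr2f2 fell by 1.44. Myl7, Myl4 and Sln did not pass and were highest on KLF15-null array 3, at 11.12, 11.33 and 9.84. Nppa too was highest there, at 13.42 against 12.29 and 11.98 on the other KLF15-null arrays and at most 11.02 in WT.

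Different probe sets of the same gene often disagreed. Of 2748 genes with 2 or more tested probe sets, 576 (21.0%) had at least 1 called higher and another called lower, against 183 with all called higher and 213 with all called lower. Across these genes, which are not independent replicates, Pearson's r between the differences of the 2 probe sets brightest in WT was 0.17. For Myh6, the α-myosin heavy chain, chosen after its values were seen, the brightest probe set differed by 0.21 and another was lower, with KLF15-null values of 3.92 to 3.95 that lie at the bottom of the scale, so that no exact difference is given. Probe sets that can cross-hybridize, marked _x_at, were higher in 60.5% and lower in 7.91% of 1074, against 20.5% and 25.0% of the 8772 plain _at probe sets. A direction given here for a gene is thus that of its probe set brightest over the 7 arrays, and genes whose probe sets were called both ways are named as such above. Of the genes called above, Cd36, Cebpb, Crat, Hlf, Hspa5, Hspa8, Klf13, Lyve1, Map1lc3b, Ndufs7, Pex11a, Ppargc1a, Rsad2, Srxn1 and Xbp1 also had at least 1 tested probe set that did not pass. No batch, hybridization date or scan order is given in the sources used here, so a batch that coincides with genotype cannot be told apart from it, and the number of arrays limits the precision.

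**Figure D3:**
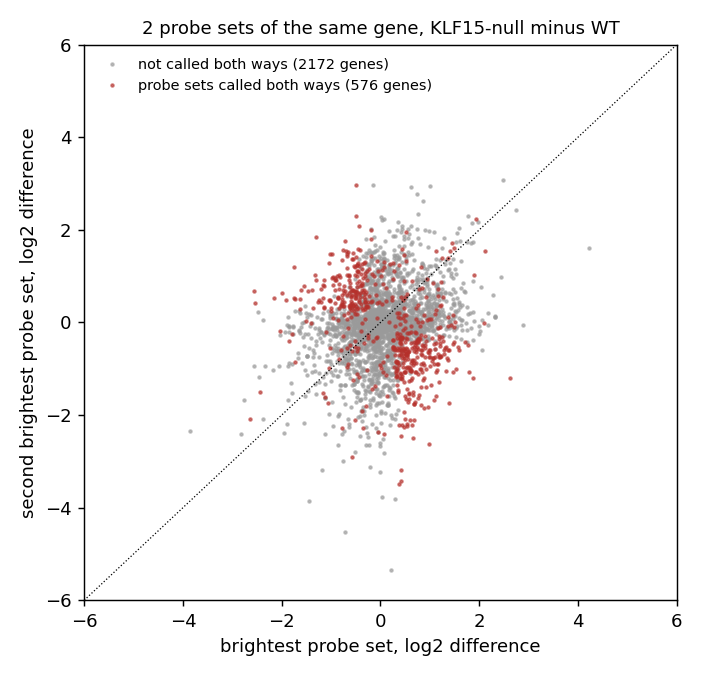
Log2 difference, KLF15-null minus WT, of the probe sets brightest (x axis) and second brightest (y axis) in WT of 2748 genes, with a point per gene and the line of equality dotted. The 576 genes with probe sets called in both directions (red) lie mostly in the upper left and lower right quadrants, and the correlation across all points is 0.17.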

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

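Single WT arrays far from the other 3 were searched for by a ratio fixed before the data were examined, the gap to the nearest array over the whole range of the 4, against its 5% critical value for 4 values; no test in this part was chosen later. Chance exceeds that value in about 5% of groups, and 6 of the 159 groups tested did; the KLF15-null group, with 3 arrays, was not tested. Gstm2 stood apart on WT array 3, at 9.86 against 9.47 to 9.51 (ratio 0.905), and all 3 KLF15-null values were lower, at 6.02 to 6.77. Ndufa5 and Pdgfrb were also highest on WT array 3, at 12.42 against 11.96 to 12.03 (ratio 0.846) and at 9.44 against 8.97 to 9.05 (ratio 0.831). The metallothionein gene Mt1 was low on WT array 1, at 11.55 against 12.17 to 12.24 (ratio 0.888), and Acsl4 was low on the same array, at 5.64 against 5.78 to 5.81 (ratio 0.837). The potassium channel gene Kcna1 was high on WT array 2, at 7.03 against 6.66 to 6.71 (ratio 0.861). Each of these genes remained past the threshold when the array in question was left out.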

How the results depend on the processing

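The mean of a gene's probe sets, leaving out genes with opposite probe sets, the 2-fold limit, leaving out _x_at probe sets, the probe set brightest in WT and the exact permutation of list means were chosen after seeing the data. The Klf15 difference ran from -2.61 to -2.45 over the alternatives and from -2.64 to -2.47 over the 7 left-out arrays. A 2-fold limit left 1026 probe sets higher and 911 lower (608 and 293 genes), which its own construction explains; all other counts stayed within 1.5 times. Over the left-out arrays they ran from 3132 to 3966 and 2763 to 3396 for probe sets, and from 1959 to 2536 and 1354 to 1741 for genes. Without WT array 3 there were 5 called lists, against 3 to 4 without any other array, oxidative phosphorylation and heat shock proteins being added as higher. The list count was 8 after quantile and 12 after cyclic loess normalization, 11 with fry and 6 with the mean of a gene's probe sets. It was 5 without _x_at probe sets and 0 with an estimated correlation or the exact permutation. The cause of these shifts in the count was not tested. Beside the 3 lists of the main comparison, fry called PPAR targets, lipid and mitochondrial regulators, ion channels, insulin signalling and white adipocyte markers lower. It called heat shock, unfolded protein and neutrophil lists higher. Adjusted p of the branched-chain, other amino acid and inflammatory lists was 0.853 with an estimated correlation and 0.0571 by exact permutation, where 35 splits and 40 lists limit it, and the other amino acid list had 0.0515 at the 60th percentile filter. Over all alternatives these p ran up to 0.853 from 5.97e-09, 0.00192 and 1.06e-07, and over the left-out arrays from 5.40e-06 to 4.87e-05, 0.00943 to 0.0267 and 2.62e-05 to 0.000247. Of 3061 combinations of 155 named genes with an alternative, 2936 kept direction and side of the threshold, 104 fell short of it, 7 newly passed and 14 reversed. Those were Cox7a1, Ckmt2 and Csrp3 after cyclic loess normalization (-0.13, -0.10 and -0.091), Hsp90aa1, Map1lc3b, Ndufs7 and Pdgfrb with gene-specific probe sets (-1.04, -0.57, -0.026 and -0.43), Rsad2, Xbp1 and Hsp90b1 with the mean of probe sets (-0.11, -0.021 and -0.82), Laptm5, Flt1 and Xbp1 with the probe set brightest in WT (-0.14, -0.63 and -1.75) and Cnp without _x_at probe sets (-0.11), where, after the first 3, another probe set or a mean stood for the gene; for the first 3 the cause was not tested. Leaving out an array took 14 genes, all with differences under 0.6 in size, below the threshold in at least 1 case: Mcm6 without any array but KLF15-null 2, Crot without any WT array or KLF15-null 2 (-0.26 there), Pex11a without WT 2 or 3 (-0.58 and -0.53), Ttn without KLF15-null 2 or 3 (-0.31 and -0.35), Rag2 without KLF15-null 3 (-0.37), and Ckmt2, Csrp3, Cox7a1, Apoa1, Apoa2, Car3, Cd4, Chga and Scd1. Alas2 passed only without WT 2 (-0.79). Replicate numbers did not pair the samples (only array pair 3 correlated best with its own number), and the replicate block gave 3039 probe sets higher and 2729 lower, 1891 and 1319 genes and 4 called lists. Offsets before taking logs were not run, since the table is on the log2 scale, and background was not measured apart from signal, so dim genes were judged only through the filter.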

Other observations

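Chosen after the results were seen were the tests of batch and of _x_at probe sets, both tests on the inflammatory genes, both on the sex-linked genes, the counts of changed probe sets and genes over other splits, and the permutation of list means.

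Among the remaining marker lists none passed camera on the deposited values, but brown adipocyte markers did after cyclic loess normalization (adjusted p = 0.0144) and white adipocyte markers with fry (adjusted p = 0.0370). The platelet chemokine genes Pf4 and Ppbp rose by 1.11 and 1.10, and the other 4 of 6 platelet markers did not pass (adjusted p = 0.737). Among brown adipocyte markers Cidea fell by 0.98 beside Ppargc1a, with 1 of 5 higher (adjusted p = 0.402), and among white adipocyte markers 3 of 6 were lower, led by Lipe (adjusted p = 0.473). Liver markers had 2 of 6 lower, Apoa1 at -0.34 and Apoa2 at -0.28 (adjusted p = 0.669), and lymphocyte markers 1 of 7 lower, Cd4 at -0.23 (adjusted p = 0.620). Nerve markers had 2 of 10 higher and 1 lower (Cnp 0.83, Chga 0.32, Kcna1 -0.52; adjusted p = 0.630). No erythroid marker of 6 and no skeletal muscle marker of 7 passed in limma, nor at an unadjusted p under 0.05 (adjusted p of the lists 0.526 and 0.737).

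Over the 35 splits of the 7 arrays into 4 and 3, only the real one (1 of 35) called any probe set or gene in limma, 6872 probe sets and 3944 genes against a highest other count of 0. This argues against chance for both counts, at the smallest share that 35 splits allow. Every other split puts the genotype difference into the spread within its groups, which lowers its count; at an unadjusted p under 0.05 the real split had 7692 probe sets and 4456 genes and the highest other 4556 and 2564. For the number of called lists chance is not argued against: 29 of 35 splits called at least 3 lists, the number of the real one, and another called 11. Camera's preset correlation of 0.01 lay below those estimated for the branched-chain, inflammatory and other amino acid lists (0.56, 0.30 and 0.036). With estimated correlations no list passed in the real split. Whether the preset raised the counts of the other splits was not tested. As the other splits mix the genotypes unequally, whether the genotype difference itself or arrays within a genotype moved the lists called there was not tested. Set against the mean of all genes, the mean difference of the branched-chain list was -0.85, and no other split gave as large a value (highest other 0.70, exact permutation p = 0.0286, the smallest possible). The same exact p was reached by the inflammatory and the other amino acid list, and in all by 20 of the 40 lists.

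The first pattern is the 576 genes whose probe sets were called in both directions, with a spread between the 2 probe sets brightest in WT (SD 1.02) far above that between 2 and 2 WT arrays (0.13 to 0.17). Array scaling as the cause is argued against by quantile normalization, which left 594 such genes, and _x_at probe sets as the whole cause by the genes without any, of which 19.6% (exact 95% interval 17.9 to 21.3) had calls both ways. Shorter RNA or cDNA fragments in the KLF15-null samples may contribute: the dimmer probe set had the lower difference in 51.8% of genes (interval 49.9 to 53.7), under the 55% set beforehand as the bound against it, but that bound was wrong by design, as the annotation holds no probe positions and brightness does not give the distance from the 3' end, a judgement made after the result was seen. A batch of labelling or scanning that coincides with genotype cannot be told apart from the genotype, since the highest correlation between the groups, 0.964, lies below all within them and no batch is given in the sources used here. A genotype difference in transcript ends or splicing stays open too and was not tested.

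The second pattern is the rise of inflammatory genes, with a mean of 1.60 (15 genes; SE over arrays 0.19). A lower share of cardiomyocytes, with all other cell types in unchanged proportion to each other, would raise the markers of those types alike. A share lowered by added myeloid cells alone would not, so this comparison cannot judge that case. Cardiomyocyte markers had a median of 0.10, and of -0.35 after cyclic loess normalization. The 45 endothelial, fibroblast and smooth muscle markers had a mean of -0.21 (SE over arrays 0.12). Genes of a list are correlated, so arrays were permuted: the 1.81 between these means (SE over arrays 0.17) was exceeded by no other split (highest other 1.48, exact p = 0.0286, the smallest possible), with the limit that the inflammatory list was chosen because it had been called. More myeloid cells may contribute and are not settled by a median of 0.36 over macrophage and monocyte markers, with Ptprc and Cd14 higher and C1qa lower. Handling of the hearts that differed between the groups, which immediate early and heat shock genes would also register, and an effect of the genotype itself stay open and were not tested.

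The third pattern is an Xist signal without signal of gene-specific Y-linked probe sets in hearts labelled as male. Y-linked probe sets that do not work on this array would leave Xist dim as in male cells, but its brightest probe set lay at or above the 82.2nd percentile on each of the 7 arrays. Hearts from female mice are a candidate explanation: none of the 9 gene-specific Y-linked probe sets, for 8 genes, exceeded the 28.6th percentile on the 7-array mean, while a cross-hybridizing _x_at probe set of Sry lay at the 53.0th. The gene-specific probe sets of Eif2s3y, Uty and Kdm5d lay at or below the 14.1st percentile on every array. With Xist bright on each array, these values argue against male hearts on all 7 arrays. The brightest Xist probe set read 9.06 ± 0.53 (SD, n = 3) in KLF15-null and 9.90 ± 0.06 (SD, n = 4) in WT hearts and the next 8.92 and 8.93, and both groups share the pattern. Whether the label or the sample is at fault was not tested.

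A chromosome segment from another strain carried along with the deleted allele could raise the share of called genes near Klf15 on chromosome 6. Of the 100 measured genes nearest to it, 50 on each side in the gene order of GRCm38.p6, 49% were called, against 46.9% of all other genes (odds ratio 1.09, 95% interval 0.72 to 1.65, Fisher's exact p = 0.688). The interval lies below the odds ratio of 2 set beforehand, so a marked excess of calls among these 100 genes is argued against. A segment that is shorter, or that changes only a few of these genes, would give no such excess and is not judged.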
